A study of Mus musculus with 12 samples.

How the data were processed

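Gene expression was measured on Illumina BeadChip arrays of 45281 probes with 1 colour (a biotin label) in 12 samples of mouse bone marrow cells. All samples carried a Bcor gene with loxP sites around exons 9 and 10 (Bcor Fl/Y) and were transduced with an empty retrovirus (control) or one that expresses Cre recombinase. The groups of 3 arrays were CD34+ control, CD34+ Cre, unsorted BM control and unsorted BM Cre. The labels give the CD34+ samples by marrow number. Number 2 was measured on 2 repeats per arm and number 4 on 1 array per arm, so each CD34+ arm holds 2 marrows. The BM samples carry repeat numbers 1 to 3, and the labels do not say whether these are separate animals.

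Per the file headers, the deposited scanner table holds an intensity and a detection p-value for each probe and array. The values show that this deposited intensity is linear, has had a background subtracted (the lowest value was −32.7 and the highest 70482) and was not scaled between arrays. The deposited detection p-value moves in steps of a rank among 936 negative controls. A value table by the authors, also deposited, holds a linear intensity scaled between arrays with low values set to 24. Its method and centring are not stated. The submitters' processing notes name RMA without a version or a role. In the authors' table the CD34+ columns kept the rank order of the scanner signal (rank correlation 0.999 or more over probes above the floor), while the BM columns reached 0.993 to 0.995. Of 83 probes at 24 in every CD34+ column whose scanner signal exceeded 500 on every BM Cre array, 78 were also at 24 in every BM column. The scanner table was therefore used here, with the authors' table as an alternative.

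Signals were corrected with normexp, using the detection p-values to estimate the negative controls, then quantile normalised and log2 transformed with an offset of 16 (neqc, limma 3.58.1, R 4.3.3). Probes with a detection p-value under 0.05 on at least 3 of 12 arrays were kept (19274). Probes were matched to gene symbols through the platform annotation and the reference gene table (assembly GRCm38.p6, used for names only). A single symbol was found for 34885 probes, several for 18 and none here for 10378. Of the kept probes, 2881 had no single symbol and were tested apart. Each gene was represented by its kept probe with the highest mean log2 intensity, which gave 10315 genes, 4063 of them with more than 1 kept probe.

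A single limma model (lmFit, then eBayes with an intensity trend) held 4 group means over 12 arrays, with 8 residual degrees of freedom and 3.78 prior ones. The comparisons were Cre minus control in CD34+ cells, Cre minus control in BM cells, the difference of those effects (CD34+ minus BM), and CD34+ minus BM in control cells. P-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was an adjusted p of 0.05. These p-values measure the spread between these samples only, and the repeats of marrow number 2 are not independent marrows. Where a probe was undetected on all arrays of a group, the fold is a lower bound ("at least"). It sets the mean of the brighter group against, on each array of the dim group, the higher of its own signal and the lowest detected signal. Where a probe was detected on 1 or 2 of the 3 arrays of a group no bound was set, and the size of a change depends on the offset.

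Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over 24 lists per comparison (96 tests in all). The estimated-correlation form and fry were run beside it. Fry asks whether the members moved, without setting them against the other genes. List tests in the alternative fits described below kept the preset correlation. The lists were PRC1.1 complex, Hoxa cluster, other Hox genes and cofactors, stem and progenitor, quiescence, S-phase and replication, mitosis, ribosome biogenesis and Myc, myeloid transcription factors, primary granule, late granulocyte, monocyte and macrophage, mast cell and basophil, eosinophil, erythroid, megakaryocyte, B cell, T and NK cell, dendritic cell and antigen presentation, stroma and endothelium, interferon response, p53 response, stress and immediate early, and cytokine and growth factor signalling. Some genes stand in several lists, such as Nkg7, Thy1, Gfi1, Gata1 and Slc6a4. The comparisons, tests, lists and the rule for named genes were fixed before the data were examined. That rule took Bcor and, for each Cre comparison, the 8 genes with the largest change each way among those past the threshold whose Cre arrays all lay on one side of all controls. It added up to 4 members of each list, by smallest p among those past the threshold, or else the member with the smallest p. For the difference of effects it took the 5 largest each way, and for the control cells the 6 largest each way, Cd34 and list members. Genes known by clone name only were counted, not named.

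Alternatives were no background correction, scaling by the median, the authors' value table, no filter or a detection limit of 0.01, the mean of a gene's probes, no intensity trend, the 6 arrays of a comparison alone, leaving out each array in turn, replicate or marrow numbers as blocks, and the repeats of number 2 averaged. Chosen after the data were seen were the CD34+ arrays of marrow number 2 only, the averaged repeats for the last 2 comparisons, and averaged repeats with number as a block. No chip or day is named in the labels, so neither was modelled. Numbers were checked for pairing by correlating deviations from the group means over genes. Same-numbered control and Cre arrays gave correlations of 0.353 to 0.502 in CD34+ cells and 0.134 to 0.429 in BM cells. Across marrow numbers 2 and 4 the CD34+ values were −0.447 to −0.399. Crossed repeats of number 2 gave 0.378 and 0.356, beside 0.372 and 0.353 for the same repeats. These values give no sign of pairing by repeat number within marrow number 2. Control and Cre BM arrays of different numbers gave −0.372 to 0.0466. Deviations within a group cancel out, so positive values for same-numbered arrays bring negative ones across numbers. The negative values therefore add no separate evidence of pairing.

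The steps were tested on simulated data made from the real group means and spreads, with 10315 genes per comparison. Of 100 genes changed by a log2 of 1, 52 were recovered for CD34+ cells, 46 for BM cells, 24 for the difference and 56 for the control cells. Of 100 changed by a log2 of 2, 93, 88, 77 and 92 were recovered in that order. False calls were 16 of 182, 10 of 162, 5 of 115 and 10 of 174 calls, and 0 of 23 unchanged lists were called. The simulated noise was independent between genes and arrays, without marrow numbers or repeats, and the unchanged lists were random genes. The simulation thus cannot show how many false calls arise among correlated genes or repeats of a marrow. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.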

Results

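The series asks, per its title, how BCOR acts on the quiescence of blood stem cells and on the growth and differentiation of myeloid cells. Bone marrow cells with a floxed Bcor gene were grown with SCF, IL-6 and IL-3 and transduced with an empty or a Cre retrovirus. RNA was profiled from CD34+ cells sorted from such cultures and from unsorted BM cells, on 3 arrays per group. Between 15571 and 16372 probes were detected on the CD34+ arrays (34.4% to 36.2%), and between 16985 and 17742 on the BM arrays (37.5% to 39.2%). Median signals of detected probes ran from 232 to 368, and the number of arrays limits the precision. Levels are log2 normalised intensities given as mean ± SD (n = 3 per group), and changes are log2 differences ± SE.

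The mast cell genes Cpa3 and Fcer1a, chosen here after their values were seen, stood near the top of the scale in every group. Mean levels of Cpa3 ran from 15.56 in CD34+ Cre to 15.75 in BM control, and those of Fcer1a from 14.96 in BM Cre to 15.68 in CD34+ control. The first principal component (60.1% of the variance) separated CD34+ from BM arrays. It also separated BM Cre arrays (70.97 to 73.15) from BM control arrays (21.26 to 30.41), so this share is not that of the populations alone. Repeats of marrow number 2 within an arm correlated at 0.994 to 0.995 over genes, against 0.957 to 0.973 between numbers 2 and 4 of the same arm.

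Bcor (probe ILMN_1228091) was lower with Cre in BM cells, at 8.60 ± 0.21 against 9.75 ± 0.20 in controls. This was a change of −1.15 ± 0.24 that left 45.0% of the control level (adjusted p = 0.00624, lower on 3 of 3 Cre arrays than on any control). In CD34+ cells the level was 9.32 ± 0.55 with Cre and 9.80 ± 0.11 in controls, a difference of −0.48 ± 0.24 that did not pass (adjusted p = 0.463). Both number 2 Cre arrays, at 8.93 and 9.08, lay below every control array, with a mean difference of −0.74 that left 59.8%. The array labelled number 4 Cre stood at 9.95 beside 9.91 for its control, a difference of 0.03. Without that array the CD34+ difference was −0.80 (adjusted p = 0.0167). The Cre arm then held only repeats of number 2, which are not independent marrows. A second detected probe (ILMN_3096287) fell by 1.27 in BM cells (adjusted p over probes = 0.00207), and in CD34+ cells it gave −0.68 for number 2 and 0.06 for number 4. A remaining Bcor probe was undetected on all arrays. The place of these probes relative to exons 9 and 10 is not known here, so they measure transcript level and do not by themselves report excision. The difference between the population effects on Bcor, 0.67 ± 0.34, did not pass (adjusted p over probes = 0.391).

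**Figure D1:**
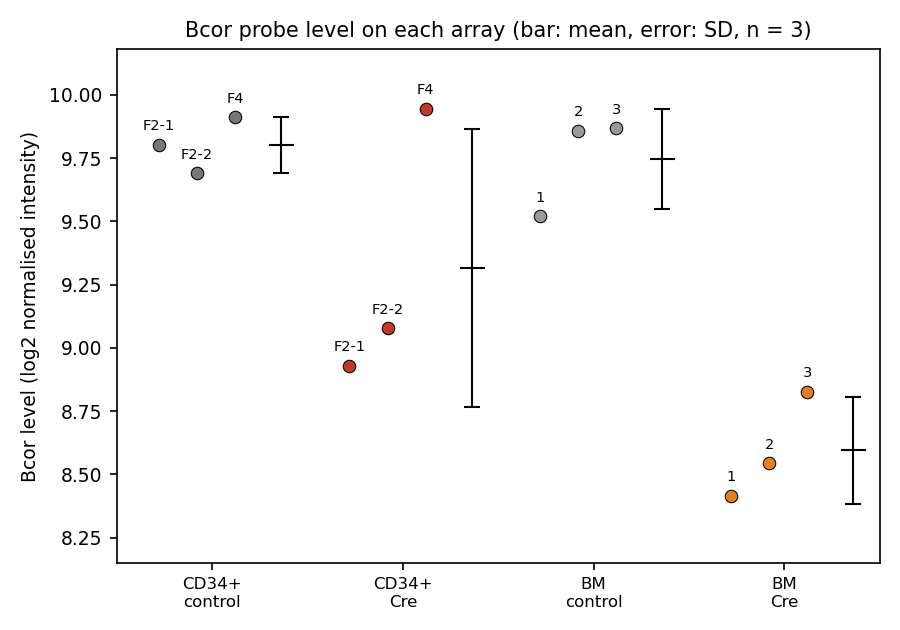
Bcor probe level on each of 12 arrays (log2 normalised intensity, y axis) by group, with replicate names, and the group mean and SD beside the points (n = 3). The array labelled number 4 Cre (F4, 9.95) lies with the controls, while the other Cre arrays lie at 9.08 or lower.

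In CD34+ cells 75 of 10315 genes changed with Cre, 47 up and 28 down. Gcnt2, a branching enzyme of poly-N-acetyllactosamine chains, rose 72.3-fold, from 5.57 ± 0.56 to 11.75 ± 0.75 (adjusted p = 5.18e-05, higher on 3 of 3 arrays). It was detected on 1 of 3 control arrays, so the fold depends on the offset. Mrgprb2, a receptor of connective tissue mast cells, fell by 5.45 ± 0.71 to 2.29% of its control level (adjusted p = 0.00372, lower on 3 of 3 arrays). Other genes with large increases were Rhobtb1 (at least 9.44-fold), Dab2ip, a Ras GTPase-activating protein (3.28 ± 0.25), and Pdlim1 (3.27 ± 0.31). The receptors Gpr65 (3.22 ± 0.53) and Gpr183 (2.53 ± 0.41), the serotonin transporter Slc6a4 (3.12 ± 0.49) and Glipr2 (2.82 ± 0.30) also rose. Among genes that fell were Fxyd6 (at least 7.96-fold), Pcp4l1 (at least 5.32-fold), Ky (at least 2.78-fold), Gmfg (−1.96 ± 0.32), Pdzk1ip1 (−1.86 ± 0.35), Thsd4 (−1.85 ± 0.32) and Cadps2 (−1.85 ± 0.36).

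Over all genes the changes of the number 2 and number 4 pairs correlated at r = 0.132. The 75 genes were called from these pairs together, with median sizes of 1.77 in number 2 and 1.18 in number 4. With marrow number as a replicate block, 268 genes passed, 67 of the 75 among them, and Fcgr1, Gp1bb and Cadps2 no longer did (adjusted p = 0.0689, 0.0536 and 0.0922). With number and repeat as the replicate block 8 passed, with number by arm as a random block 2, and with the repeats averaged 11. With the 6 CD34+ arrays fitted alone 18 passed. Leaving out an array of number 2 gave 25 without control F2-1, control F2-2 or Cre F2-1, and 26 without Cre F2-2. Leaving out the number 4 control gave 118, and leaving out the array labelled number 4 Cre gave 1051, all 75 among them. Without either array its arm held only repeats of number 2, which are not independent marrows. These counts thus rest in part on the spread between repeats. Of the 20 called genes named for this comparison, 8 passed without any 1 array: Gcnt2, Rhobtb1, Dab2ip, Pdlim1, Glipr2, Ltb4r1, Fxyd6 and Mrgprb2. The other 12 missed the threshold without at least 1 number 2 array, with adjusted p = 0.0529 to 0.217. Of these 8, Mrgprb2 (adjusted p = 0.126) and Ltb4r1 (adjusted p = 0.0624) missed it with the repeats averaged. Rhobtb1, Glipr2, Fxyd6 (adjusted p = 0.0597 each) and Pdlim1 (adjusted p = 0.0721) missed it with number and repeat as the replicate block. With number by arm as a random block Gcnt2 and Mrgprb2 passed, and the other 6 did not (adjusted p = 0.139 to 0.572). Over the alternatives adjusted p ran from 3.39e-06 to 0.0460 for Gcnt2 and from 5.33e-04 to 0.126 for Mrgprb2.

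Few list members changed in CD34+ cells. In the late granulocyte list 1 of 29 rose, the leukotriene B4 receptor Ltb4r1 (1.90 ± 0.22, adjusted p = 0.00245). In the monocyte and macrophage list 1 of 29 rose, the Fc receptor Fcgr1 (at least 2.01-fold). In the megakaryocyte list 2 of 21 rose, Slc6a4 and the platelet glycoprotein Gp1bb (at least 1.28-fold), and Slc6a4 was the 1 of 25 mast cell and basophil genes that rose. In the erythroid list 1 of 18 fell, carbonic anhydrase Car2 (−1.51 ± 0.27). No member of the other 19 lists passed. The stem cell list's lowest p was that of the transcription factor Sox4 (2.37 ± 0.61, adjusted p = 0.135). The quiescence list's was that of Ndn (1.43 ± 0.45, adjusted p = 0.241), and that of S-phase Mcm2 (0.55 ± 0.38, adjusted p = 0.599). Adjusted over the list alone, counts were 2 up and 2 down for mast cell and basophil and 2 up and 1 down for megakaryocyte. They were 1 up and 1 down each for stem and progenitor and for monocyte and macrophage, and 1 up for PRC1.1 complex, primary granule, late granulocyte and stroma and endothelium. They were 1 down for erythroid, T and NK cell, and dendritic cell and antigen presentation.

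As sets, only the ribosome biogenesis and Myc list passed camera in CD34+ cells, upward, with a median of 0.36 and 0 of 27 members past the threshold (adjusted p = 0.0172). This call was lost with an estimated correlation (adjusted p = 0.862), without control F2-1 (adjusted p = 0.0833) or control F2-2 (adjusted p = 0.105), and with the repeats averaged (adjusted p = 0.173). The S-phase and replication list had a median of 0.21 and the mitosis list 0.20, and neither passed (adjusted p = 0.284 and 0.448). Both passed without the array labelled number 4 Cre (adjusted p = 7.97e-07 and 9.17e-05) and with marrow number as a replicate block (adjusted p = 0.00273 and 2.65e-04), and their highest over the alternatives were 0.947 and 0.862. They also passed without control F2-1 (adjusted p = 0.0273 for both) or control F2-2 (adjusted p = 0.0497 for both). All these fits kept the preset correlation of 0.01, while the estimates were 0.838 for S-phase and 0.846 for mitosis. With the estimated correlation on all arrays neither list passed (adjusted p = 0.862 for both). In every fit without the array labelled number 4 Cre, the Cre arm held only repeats of number 2. Calls gained there do not rest on independent marrows. The interferon response list (median −0.32, adjusted p = 0.107) passed downward without the array labelled number 4 Cre (adjusted p = 0.00504) and with that block (adjusted p = 0.0263). The primary granule list (median 0.19, adjusted p = 0.0609) passed upward with that block (adjusted p = 0.0191), without control F2-2 (adjusted p = 0.0497) and without Cre F2-1 (adjusted p = 0.0397). Adjusted p over the alternatives ran up to 0.862 for interferon response and 0.552 for primary granule. With number as a replicate block and the repeats averaged, mitosis (adjusted p = 0.00570) and primary granule (adjusted p = 0.0160) passed, and S-phase and interferon response did not (adjusted p = 0.172 for both). Median, mean and test differed in sign for stem and progenitor (−0.01, 0.05, up), myeloid transcription factors (−0.03, 0.05, up) and dendritic cell and antigen presentation (0.01, −0.04, down). By fry, members changed in either direction in the megakaryocyte (adjusted p = 0.00343), mast cell and basophil (adjusted p = 0.0447) and stem and progenitor (adjusted p = 0.0447) lists, and none of the 24 moved one way (lowest adjusted p = 0.155).

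**Figure D2:**
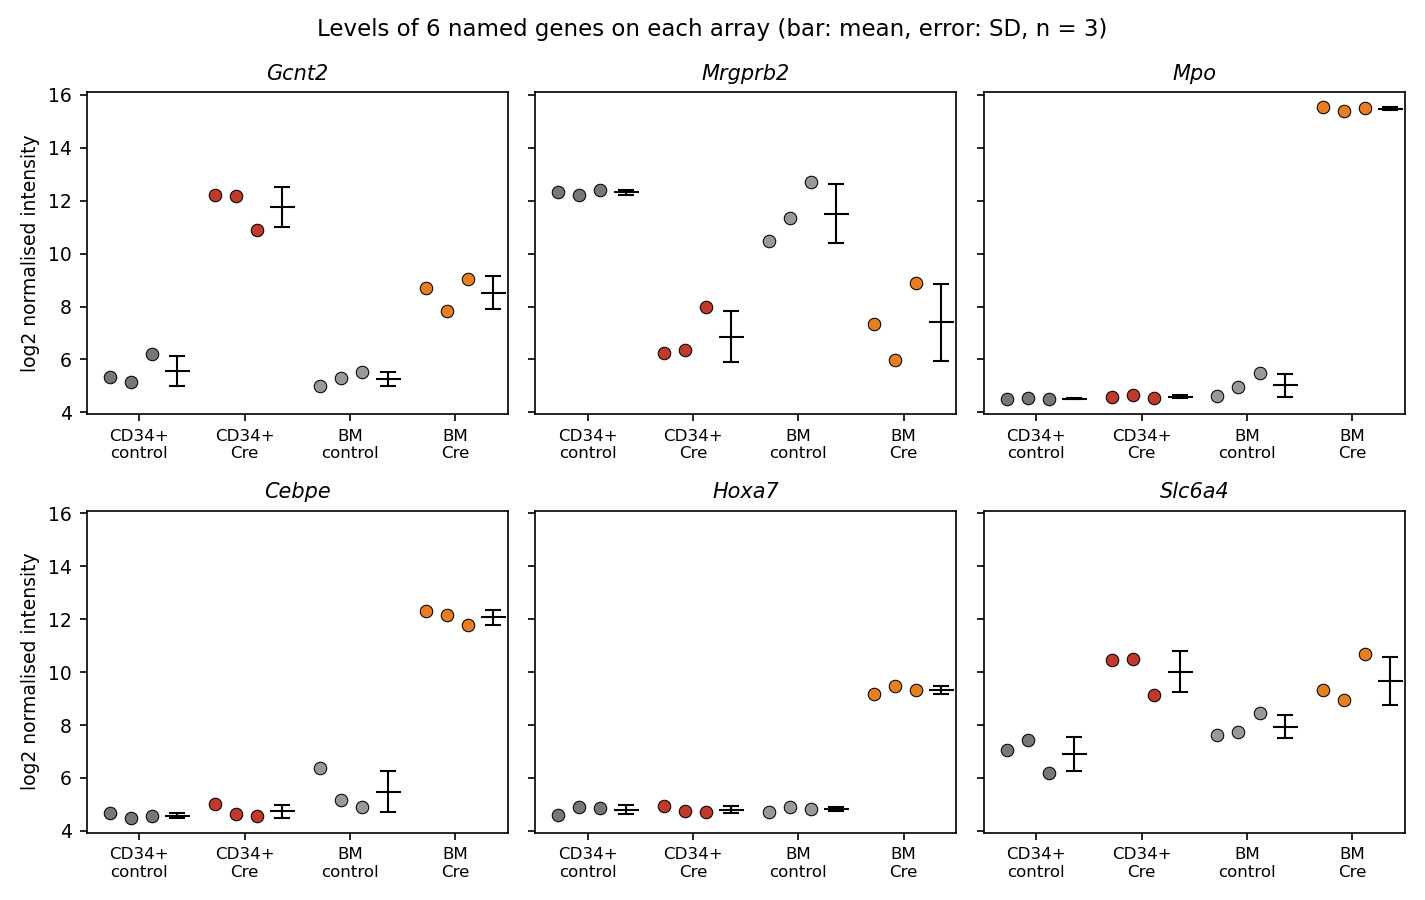
Levels of 6 named genes (log2 normalised intensity, y axis) on the 3 arrays of each group, with mean and SD. Gcnt2, Mrgprb2 and Slc6a4 moved with Cre in both populations, and Mpo, Cebpe and Hoxa7 in BM cells.

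In unsorted BM cells, 1725 genes changed with Cre, 886 up and 839 down, and granulocyte genes showed the largest rises. Myeloperoxidase, Mpo, rose by 10.45 ± 0.21, from 5.02 ± 0.45 to 15.47 ± 0.07 (adjusted p = 4.64e-11, higher on 3 of 3 arrays). It was detected on 1 of 3 control arrays, as was Cebpe, so the size of these rises depends on the offset. The neutrophil serine proteases Prtn3 and Elane, undetected in the controls, rose at least 443-fold and at least 295-fold. The primary granule list had 8 of 13 members up and none down, with a median of 3.37 (2.91 with bounds), and passed with either correlation (adjusted p = 1.29e-14 and 0.00101). Other genes with the largest rises were Prg3 (6.77 ± 0.42), Nkg7 (at least 74.6-fold), Plac8 (6.61 ± 0.20), Cebpe (6.59 ± 0.33) and the eosinophil peroxidase Epx (6.53 ± 0.44).

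In the late granulocyte list 28 of 29 members rose and none fell, with a median of 4.52 (adjusted p = 8.38e-37, and 0.0174 with an estimated correlation). Among them were Trem3 (at least 50.8-fold), Pglyrp1 (5.95 ± 0.17), haptoglobin, Hp (at least 36.8-fold), and Chil1 (5.61 ± 0.22). These sizes and bounds hold for the brightest probe of each gene. Other probes rose less, by 3.02 and 4.01 for Hp against 5.80, and by 2.35 for Pglyrp1. Over 30 other probes of genes changed 16-fold, the median share of the log2 difference held was 79.0%. In the eosinophil list 6 of 8 rose, among them the ribonuclease Ear6 (5.82 ± 0.58) and Alox15 (4.04 ± 0.27), and 1 fell. That call (adjusted p = 3.53e-07) was lost with an estimated correlation (adjusted p = 0.0704) and passed by fry (adjusted p = 3.58e-05). In the myeloid transcription factor list 10 of 26 rose and 2 fell, and the call held with either correlation (adjusted p = 0.0024 and 0.0338). Cebpe, a regulator of late granulocyte genes, Cebpa, a regulator of granulocyte commitment (at least 4.59-fold), Id1 (4.84 ± 0.59) and Gfi1 (1.38 ± 0.17) rose. In the Hoxa cluster 3 of 5 measured genes rose, Hoxa7 (at least 15.9-fold), Hoxa5 (at least 5.49-fold) and Hoxa9 (at least 2.26-fold), all undetected in controls. The Hoxa call held with either correlation (median 1.46, 1.18 with bounds, adjusted p = 1.14e-04 and 0.0254). Among the other Hox genes and cofactors, 1 of 11 rose, Hoxb4 (1.43 ± 0.26), and 2 fell, Meis1 (−0.86 ± 0.16) and Pknox1 (−0.55 ± 0.17), without a set call (adjusted p = 0.747).

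Markers of other lineages moved as well. Of the monocyte and macrophage list 9 of 29 rose, among them Ly6c1 (5.59 ± 0.36), Arg1 (5.27 ± 0.61) and Cd14 (3.02 ± 0.23), and none fell. Of the erythroid list 7 of 18 rose, among them Car1 (at least 9.36-fold) and the transcription factor Klf1 (3.02 ± 0.23), and 1 fell. Both calls (adjusted p = 4.10e-05 and 0.00127) were lost with an estimated correlation (adjusted p = 0.297 and 0.253) and passed by fry (adjusted p = 0.00807 and 0.00134). Of the T and NK cell list 3 of 8 rose, Nkg7, Thy1 (at least 5.41-fold) and Il7r (1.79 ± 0.50). That call (adjusted p = 0.0116) was lost with an estimated correlation (adjusted p = 0.0704) and with repeat number as a replicate block (adjusted p = 0.0625). It passed by fry (adjusted p = 8.30e-07), and over the alternatives its adjusted p ran up to 0.998. Of the stroma and endothelium list 4 of 7 rose, Acta2 (4.83 ± 0.27), Igfbp4 (3.05 ± 0.35), Thy1 and Vcam1 (at least 3.05-fold). Another Acta2 probe rose by 2.55. Pecam1, the other member past the threshold and chosen here after its value was seen, fell by 0.67. This call held with either correlation (adjusted p = 0.00179 and 0.0349).

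Mast cell and basophil genes went both ways, with 5 of 25 up and 11 down. The basophil proteases Prss34 (6.52 ± 0.66) and Mcpt8 (3.24 ± 0.41) rose, as did Hgf (4.70 ± 0.36), while Tph1, which makes serotonin in mast cells, fell by 0.99 ± 0.12. The list's median was −0.39 and its mean 0.13, and the test, downward, did not pass (adjusted p = 0.054, and 0.679 with an estimated correlation). It passed without BM Cre 3 (adjusted p = 0.0225), with the mean of probes (adjusted p = 0.0445) and without a filter (adjusted p = 0.0282). Mrgprb2 fell here too (−4.10 ± 0.71, 5.84% left), beside Tspan8 (−3.51 ± 0.57), Sytl2 (−3.09 ± 0.26), Golm2 (−3.07 ± 0.17), Trib3 (−3.03 ± 0.84), Dnase2b (−2.77 ± 0.46), Slc1a4 (−2.67 ± 0.59) and Bace2 (−2.64 ± 0.36).

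Of the stem and progenitor list 6 of 22 rose and 6 fell, and the set did not pass (adjusted p = 0.615, median −0.02, mean 0.18). Thy1, Cd27 (at least 4.00-fold) and Prom1 (at least 2.86-fold) rose, and Tal1 (−1.05 ± 0.16) and Meis1 fell. The quiescence list had 1 of 20 up and 4 down. Txnip, an inhibitor of thioredoxin (−1.25 ± 0.28), Fbxw7 (−0.67 ± 0.19) and the retinoblastoma gene Rb1 (−0.45 ± 0.11) fell, and Gfi1 rose. In the S-phase and replication list 1 of 30 rose, Dut (1.05 ± 0.25), and in the mitosis list 1 of 25, Ttk (0.58 ± 0.16), a count of 0 adjusted over the list alone. Quiescence passed downward (median −0.53, adjusted p = 0.0336), and S-phase (median 0.40, adjusted p = 0.0424) and mitosis (median 0.43, adjusted p = 0.0252) upward. With an estimated correlation none of the 3 did (adjusted p = 0.433, 0.764 and 0.764). By fry quiescence passed (adjusted p = 0.0340), and S-phase and mitosis did not (adjusted p = 0.558 and 0.495). Quiescence missed the threshold without BM control 3 (adjusted p = 0.0655) or BM Cre 2 (adjusted p = 0.145). S-phase missed it without control 1 (adjusted p = 0.0683), control 2 (adjusted p = 0.0607), Cre 1 (adjusted p = 0.101) or Cre 2 (adjusted p = 0.259). Mitosis missed it without control 2 (adjusted p = 0.0607) or Cre 2 (adjusted p = 0.0597). Over the alternatives the adjusted p ran from 0.00871 to 0.433 for quiescence, 7.96e-04 to 0.764 for S-phase and 3.74e-07 to 0.764 for mitosis.

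Of the remaining 9 lists none passed camera in BM cells (lowest adjusted p = 0.152). The megakaryocyte list had 4 of 21 up and 6 down, among them von Willebrand factor, Vwf (−1.66 ± 0.28), and Rgs18 (−1.27 ± 0.20). The dendritic cell list had 5 of 15 up, such as the class II gene H2-Aa (at least 3.46-fold), and 4 down, such as the lectin Clec10a (−2.00 ± 0.22). The cytokine list had 6 of 26 down, such as Spred1 (−1.49 ± 0.21), and 1 up, the G-CSF receptor Csf3r (3.61 ± 0.26). It passed downward without BM Cre 1 (adjusted p = 0.0406), with up to 0.699 over its alternatives. The stress list had 6 of 27 down, such as heme oxygenase Hmox1 (−1.51 ± 0.33) and Trib3, and 1 up. The p53 list had 3 of 31 up and 4 down, and the interferon list 1 of 21 up and 2 down, Usp18 (−1.40 ± 0.23) and Ifi27 (−1.55 ± 0.31). Of 6 B cell genes 1 rose, Igll1 (at least 1.40-fold). Of the PRC1.1 complex Bcor was the 1 of 12 that fell. None of the 27 ribosome biogenesis genes passed, and that list passed upward without BM control 2 (adjusted p = 0.0463) or BM Cre 3 (adjusted p = 2.69e-06), with up to 0.889 over its alternatives. Median, mean and test differed in sign for PRC1.1 complex (0.03, −0.08, down). Adjusted over the list alone, counts were 10 up and 1 down for primary granule, 9 up and 1 down for erythroid, 7 up and 1 down for eosinophil, 10 up for monocyte and macrophage and 5 up and 14 down for mast cell and basophil. They were 7 up and 8 down for stem and progenitor, 5 up and 8 down for megakaryocyte, 10 up and 3 down for myeloid transcription factors, 7 up and 4 down for dendritic cell and 5 up and 4 down for p53 response.

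With repeat number as a replicate block 2839 genes passed in BM cells, 1699 of the 1725 among them. Leaving out BM control 3 gave 1126 genes and leaving out BM Cre 1 gave 1143. With the values of the authors' table, 837 genes passed, 719 of them shared, and 44 of the 81 called genes named for this comparison missed the threshold. Mpo, Prtn3, Cebpe, Epx, Hoxa7, Hoxa5 and Hoxa9 were among those 44, and these 7 showed a change of 0 there. Of the 12 set calls in BM cells 10 were lost with that table (adjusted p = 0.0705 to 0.998), all but primary granule and quiescence. Of 81 called genes named for this comparison, 69 passed without any 1 array. The other 12 (Il7r, Dut, Gadd45a, Ttk, Rb1, Pknox1, Bcl2l1, Ifi47, Atf4, Fbxw7, Trib3 and Pmaip1) had adjusted p = 0.0503 to 0.154 without some array.

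**Figure D3:**
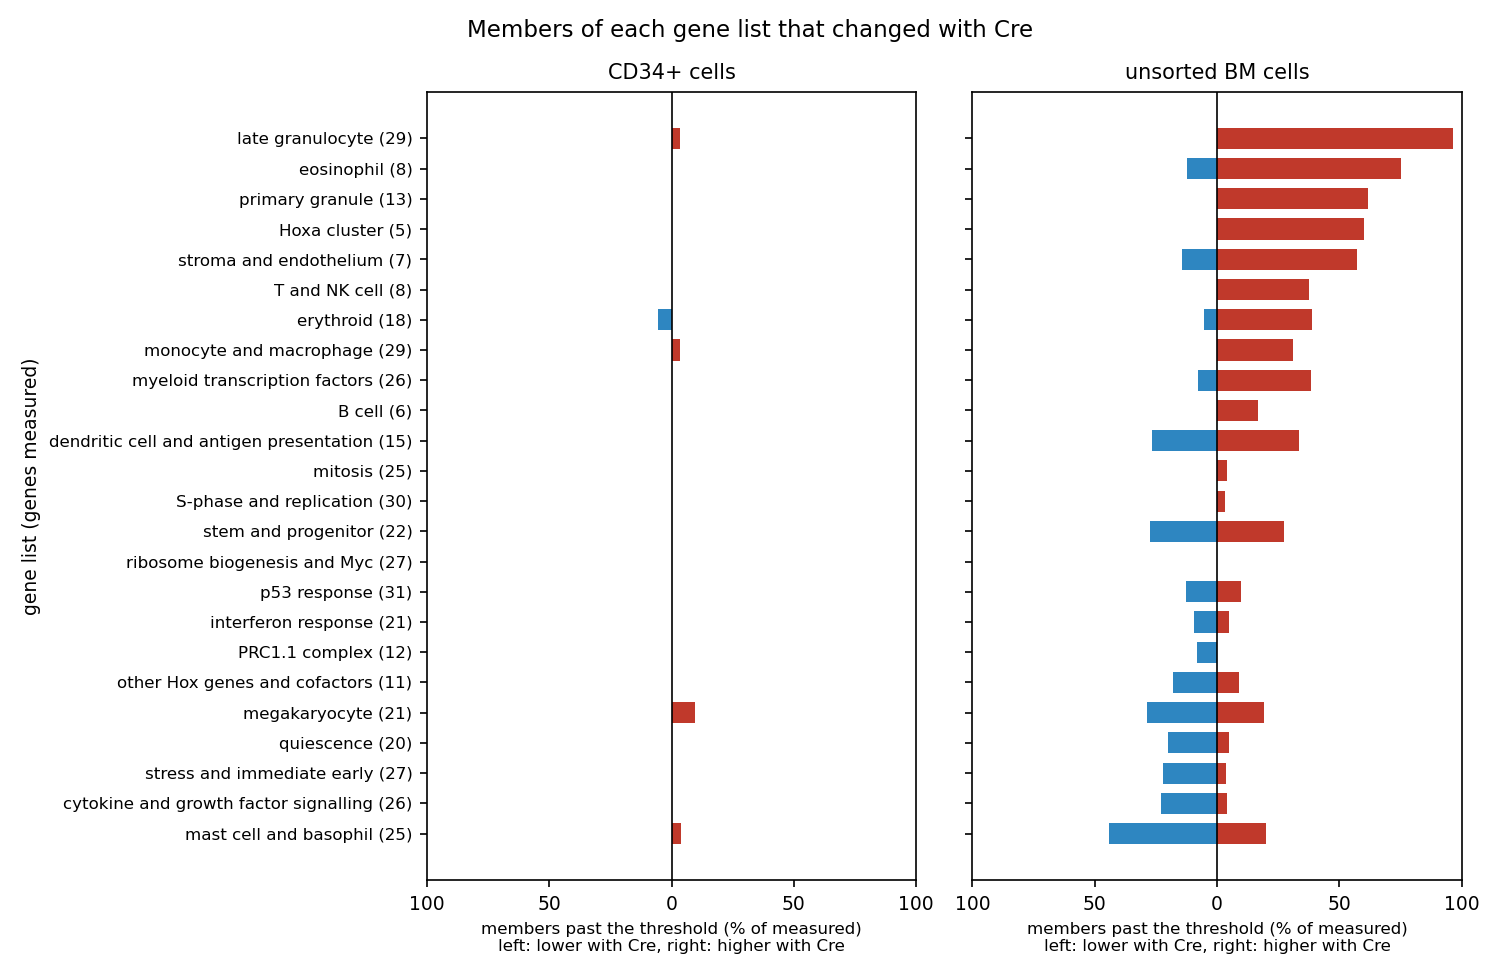
Share of the measured members of each list past the threshold (%, x axis), higher (right) or lower (left) with Cre, in CD34+ cells (left panel) and BM cells (right panel). In BM cells 28 of 29 late granulocyte genes rose, against 1 of 29 in CD34+ cells.

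The Cre effects in both populations were compared across genes. Of the 47 genes that rose in CD34+ cells 33 also rose in BM cells, where 4.04 are expected by independence (two-sided Fisher's exact p = 4.02e-25, genes taken as independent, which they are not). Rhobtb1, Dab2ip, Gcnt2 (6.18 and 3.25), Pdlim1 (3.27 and 5.46) and Plac8 (2.14 and 6.61) were among them. Of the 28 that fell 8 also fell, against 2.28 expected (two-sided Fisher's exact p = 0.00132), with Mrgprb2 (−5.45 and −4.10) and Fxyd6 among them. Another 4 moved in opposite directions, 6.23 being expected, among them Car2 (−1.51 and 1.18). Of the 75 genes, 61 had the same sign in BM cells. Over all 10315 genes, which are not independent replicates, the effects correlated at r = 0.343 (rho = 0.379). The planned test drew 100 of the 200 distinct relabelings of control and Cre within the populations. Of these, 5 gave a correlation at least as large in size, the real one included (two-sided permutation p = 0.05, not under 0.05). All 100 ways to split the arrays of each population 3 against 3 were also counted, which was not the planned test. Of these splits 4 did, the real one included (two-sided exact permutation p = 0.04). Of the 16 that part each same-numbered pair, a test chosen after the result was seen, 2 did (two-sided exact permutation p = 0.125, with 0.0625 as the smallest possible).

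**Figure D4:**
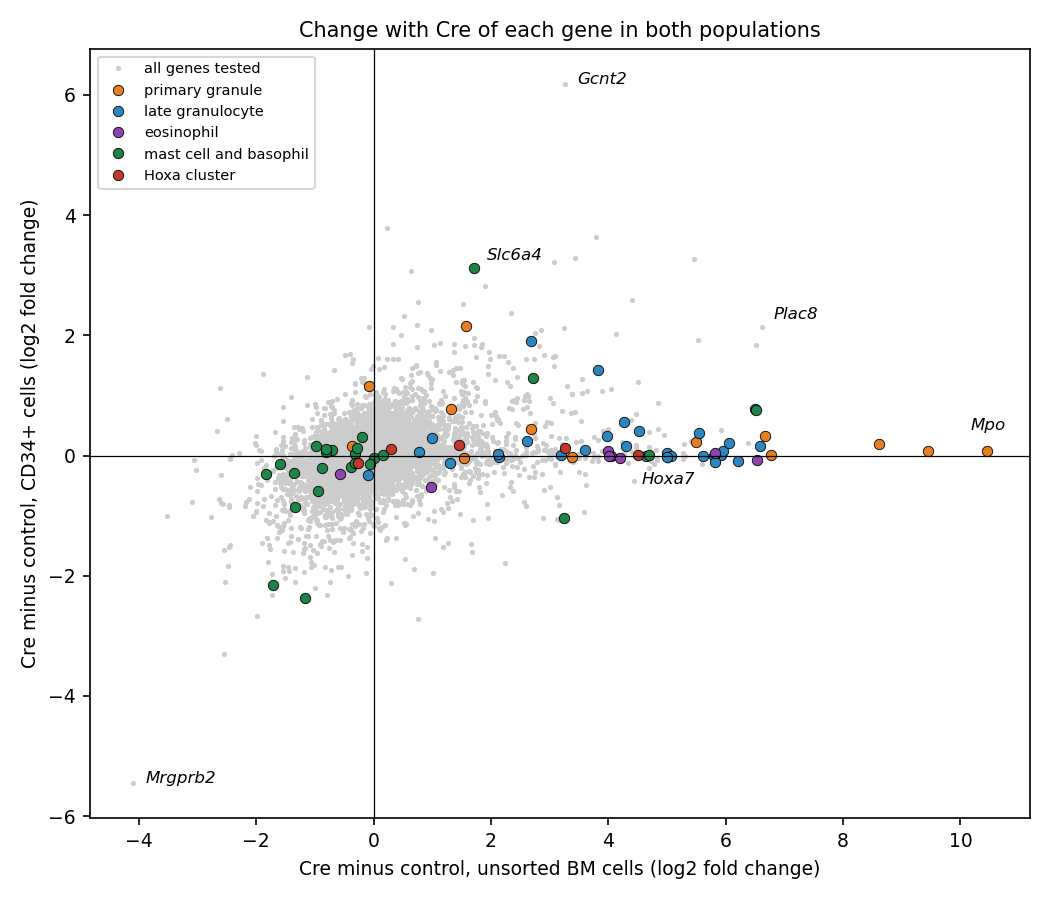
Change with Cre (log2 fold change) of each of 10315 genes in BM cells (x axis) and CD34+ cells (y axis), with the members of 5 lists in colour. Right of 0 on the x axis lie 11 of 13 primary granule and 28 of 29 late granulocyte genes, with medians on the y axis of 0.19 and 0.06. Mpo lies at 10.45 and 0.08, and Gcnt2 and Mrgprb2 lie far from 0 on both axes.

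The effect of Cre differed between the populations for 593 genes, 168 with a larger value in CD34+ cells and 425 with a smaller one. Largest in the second group were Mpo (−10.38 ± 0.30), Prtn3 (−9.36 ± 0.28), Elane (−8.43 ± 0.33), the granule protein Prg3 (−6.77 ± 0.59) and Epx (−6.61 ± 0.62). Of these, Mpo, Prtn3, Prg3 and Epx were undetected on all 6 CD34+ arrays and Elane on 5, so the sizes depend on the offset. In the first group Gcnt2 rose further in CD34+ cells (2.92 ± 0.58 more), and Golm2 (2.99 ± 0.25), Fam155a (2.41 ± 0.52), Gpm6a (2.38 ± 0.37) and Aldh1l2, a mitochondrial folate enzyme (3.74 ± 0.98), fell in BM cells and did not pass in CD34+ cells. Golm2 and Gpm6a were undetected on all CD34+ arrays. With the repeats of number 2 averaged, Gcnt2 (adjusted p = 0.0876), Fam155a (adjusted p = 0.0629) and Aldh1l2 (adjusted p = 0.209) missed the threshold. With the values of the authors' table, all of these 10 genes missed it but Gcnt2 and Elane, and Mpo, Prtn3, Prg3, Epx, Golm2 and Gpm6a showed a difference of 0. Aldh1l2 (adjusted p = 0.0463) missed the threshold in 9 of the 12 fits that left out 1 array, all but those without the array labelled number 4 Cre, CD34+ control F4 or BM Cre 2, with adjusted p from 2.00e-04 to 0.117.

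By list, a smaller effect in CD34+ cells passed for 24 of 29 late granulocyte genes, 8 of 13 primary granule genes, 6 of 8 eosinophil genes, 3 of 5 Hoxa genes, 5 of 26 myeloid transcription factors and 2 of 8 T and NK cell genes. In the stroma and endothelium list 3 of 7 had a smaller and 1 a larger effect. These 7 set calls (adjusted p = 7.77e-42, 1.72e-14, 1.55e-09, 1.93e-05, 0.00182, 1.22e-04 and 6.26e-04 in that order) held with an estimated correlation (adjusted p = 0.0116, 0.00105, 0.0346, 0.0143, 0.0210, 0.0145 and 0.0210). The monocyte and macrophage call (5 of 29 smaller) and the erythroid call (4 of 18 smaller), both at adjusted p = 2.14e-04, were lost with it (adjusted p = 0.399 and 0.175). By fry the erythroid list passed (adjusted p = 0.00747) and the monocyte and macrophage list did not (adjusted p = 0.0821). With the values of the authors' table all 9 calls were lost (adjusted p = 0.0874 to 0.985), and the stroma and endothelium call also without a filter (adjusted p = 0.0525). The other 15 lists did not pass, among them mast cell and basophil (4 of 25 larger, 3 smaller, median 0.36, mean −0.23, test upward), quiescence (0 of 20 larger, 1 smaller) and mitosis (0 of 25). Median, mean and test also differed in sign for stem and progenitor (0.13, −0.13, down) and interferon response (0.17, −0.07, down). Blocked within each population 949 genes passed, 573 of the 593 among them. With the repeats of number 2 averaged 316 passed, with number 2 only 1175, and 210 with the values of the authors' table. With number 2 only, each CD34+ arm held repeats of a single marrow. Mitosis passed with the replicate block (adjusted p = 0.00613), without CD34+ control F4 (adjusted p = 5.25e-04), Cre F2-1 (adjusted p = 0.0289) or Cre F2-2 (adjusted p = 0.0197), and ran up to 0.935 over its alternatives. Stress genes (adjusted p = 0.0728, median 0.39) and cytokine genes (adjusted p = 0.244, median 0.39) passed upward with the block as well (adjusted p = 0.0384 and 0.0371), and ran up to 0.668 and 0.784. Stress genes also passed without CD34+ Cre F2-1 (adjusted p = 0.0278), CD34+ Cre F2-2 (adjusted p = 0.0207), BM control 1 (adjusted p = 0.0442) or BM Cre 1 (adjusted p = 0.0299). S-phase genes (median −0.17) passed downward without CD34+ control F4 (adjusted p = 0.0405) or Cre F2-2 (adjusted p = 0.0488), with up to 0.952 over the alternatives. Dendritic cell genes passed downward without the array labelled number 4 Cre (adjusted p = 0.0311), with up to 0.985. That fit held only repeats of number 2 in the CD34+ Cre arm. Ribosome biogenesis genes passed upward without BM Cre 2 (adjusted p = 0.0299) and downward without BM Cre 3 (adjusted p = 0.0180), with up to 0.979.

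Control cells of the sorted and unsorted populations differed at 3916 genes, 2085 higher and 1831 lower in CD34+ cells. The sort is confounded here with any other difference between the populations. Cd34 itself did not differ, at 10.26 ± 0.19 in CD34+ and 10.17 ± 0.16 in BM cells (0.09 ± 0.25, adjusted p = 0.823). The Fc receptor gamma chain gene Fcer1g stood at 15.33 ± 0.05 in CD34+ cells and was undetected in BM cells by its 1 probe (at least 1026-fold higher). Its log2 difference was 10.80 in control and 10.84 in Cre arrays, sizes that depend on the offset. With its 1 probe, an effect of the probe cannot be told apart from a difference in the gene. Cd59a (5.55 ± 0.44), Lrrc57 and Gpr137b-ps (both at least 26.8-fold), Arl11 (4.33 ± 0.25) and the homeobox gene Meis2 (4.29 ± 0.77) were also higher. Among the genes lower in CD34+ cells were major basic protein, Prg2 (at least 73.3-fold), Ear3 (at least 69.4-fold), S100a8 (at least 46.6-fold) and Slpi (at least 63.3-fold). The platelet factor Pf4 (at least 38.2-fold) and the macrophage gene Gpnmb (−5.76 ± 1.30) were lower too. These sizes and bounds hold for the brightest probe of each gene. Other Ear3 probes gave −2.55 and −2.87 against −7.01, and other Gpnmb probes −2.61 and −1.03. With the values of the authors' table Prg2, Ear3, S100a8 and Pf4 showed a change of 0, and Slpi and Gpnmb turned direction. Of the 86 called genes named for this comparison 28 missed the threshold with the same direction, and 3 missed it and turned direction. On the BM control arrays Prg2 and Ear3 varied with SDs of 1.52 and 1.61.

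By list, 17 of 29 late granulocyte genes were lower and 1 was higher, and 18 of 29 monocyte and macrophage genes, such as Fcgr3 (−2.61 ± 0.27), and 5 of 8 eosinophil genes were lower. Of the p53 response list 10 of 31 were higher, such as the death receptor Fas (1.74 ± 0.29), and Zmat3 was lower (−1.24 ± 0.24). These 4 calls (adjusted p = 6.80e-05, 7.46e-06, 0.00164 and 0.0249) were all lost with an estimated correlation (adjusted p = 0.863, 0.863, 0.863 and 0.909). By fry they passed in the same direction (adjusted p = 0.00259, 0.00259, 0.00187 and 0.0138). Fry also passed 6 lists that camera did not. All 4 calls were lost with the values of the authors' table (adjusted p = 0.888, 0.499, 0.897 and 0.214). Medians of the first 3 were −0.90, −1.34 and −3.00 (−0.53, −0.87 and −2.19 with bounds), and that of the p53 list 0.50. The p53 call was also lost without BM control 1 (adjusted p = 0.0573), with median scaling (adjusted p = 0.0739) and with the mean of probes (adjusted p = 0.130), and over its alternatives ran up to 0.909. In lists that did not pass, 8 of 30 S-phase genes were lower, such as Pcna (−3.31 ± 0.21). That list passed without CD34+ control F2-1 (adjusted p = 0.0219) or F2-2 (adjusted p = 0.0236), with the repeats averaged (adjusted p = 0.0177), the 6 arrays alone (adjusted p = 0.0367), median scaling (adjusted p = 0.0151) or no filter (adjusted p = 0.0241), and ran up to 0.958. Of the mitosis list 5 of 25 were lower, such as Ccna2 (at least 2.93-fold), and 1 was higher. Of all 10315 genes 1831 were lower and 2085 higher, so such counts do not set this list apart. Of the mast cell and basophil list 8 of 25 were lower, such as Ms4a2 (−1.23 ± 0.15), and 3 were higher, and of the primary granule list 4 of 13 were lower and 2 higher. Of the interferon list 8 of 21 were higher, such as Zbp1 (1.28 ± 0.17), and 1 was lower. Median, mean and test differed in sign for Hoxa cluster (−0.02, 0.35, up), quiescence (0.03, −0.01, down), B cell (−0.05, 0.09, up), T and NK cell (−0.03, 0.04, down), ribosome biogenesis and Myc (0.00, 0.01, down) and dendritic cell (−0.04, 0.04, up). Scaling by the median put the median over all genes at 0.30, against 0.07, and gave 4744 genes, 3329 of them higher. With the values of the authors' table, the count was 2486, 945 of them higher. Population is confounded with any difference in culture, day or chip, since the labels name none.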

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

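The tests of granulocytic cells diluting mast-like cells and of the CD34 sort were chosen only after the results they measure were seen. So were the relabelings that keep the pairs and the sign comparisons over genes chosen by BM cells alone. The sign comparisons between Cre arrays of numbers 2 and 4 were part of the rule fixed beforehand, and setting them aside was not.

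The effect of Cre differed between CD34+ and BM cells, by a test of the difference itself, for 593 genes. With the largest differences each way were Mpo (−10.38), Prtn3 (−9.36), Elane (−8.43), Prg3 (−6.77) and Epx (−6.61), and Aldh1l2 (3.74), Golm2 (2.99), Gcnt2 (2.92), Fam155a (2.41) and Gpm6a (2.38). Mpo, Prtn3, Prg3, Epx, Golm2 and Gpm6a were undetected on all 6 CD34+ arrays, so these sizes depend on the offset, and with the authors' table these 6 showed a difference of 0. With the repeats of number 2 averaged, Aldh1l2, Gcnt2 and Fam155a no longer passed (adjusted p = 0.209, 0.0876 and 0.0629). Chance was not excluded for this count by relabeling control and Cre within the populations. Of 100 relabelings 6 gave as many genes, the real one included, and the highest of the others gave 2403. The other 5 were all among 6 relabelings that left the BM arms as they are, which gave 492 to 2403 genes, while 93 that changed the BM arms gave 0. These relabelings exchange arrays across the numbers that pair them. Of the 32 that part each same-numbered pair 5 gave as many genes, the real one included, with 1515 as the highest other. Relabelings that keep the BM arms keep the large BM effect in the comparison, and those that change them put it into the spread. By this construction they cannot show whether the count of 593 arose by chance.

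Among probes without a gene name, which the comparisons of genes leave out, some were higher with Cre past the threshold. Of 2881 such probes these were 5 in CD34+ cells and 157 in BM cells, while 13 and 207 were lower. The shares past the threshold, 0.625% and 12.6%, stood beside 0.616% and 14.3% of named probes.

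For the counts within a population, 3 against 3 arrays make 10 splits, too few for a share under 0.05. For Cre in CD34+ cells 1 of 10 splits gave as many as the 75 genes, the real one, and the highest other gave 0. For Cre in BM cells 1 of 10 gave as many as 1725, with 0 as the highest other. For control cells of both populations 1 of 10 gave as many as 3916, with 0 as the highest other. Every other split mixes the groups compared and so puts a real effect into the spread. By this construction the counts of 0 cannot show whether the real counts arose by chance.

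The array labelled number 4 Cre kept Bcor at the level of its control. A wrong label, cells without Cre, was not excluded by the rule fixed beforehand, which asked for a larger share than in every same-arm comparison. The test took 64 genes that changed at least 4-fold with Cre in BM cells. These moved the same way by at least 2-fold in the number 2 pairs. In the number 4 pair 50 of them (78.1%) had the same sign, against at most 56.2% in the 4 same-arm comparisons without that array. The number 2 Cre arrays, which chose those genes, gave 82.8% and 79.7% against the number 4 Cre array, so the rule was not met. Either reading would give such values. Over the 315 genes chosen by BM cells alone, 70.8% had the BM sign in the number 4 pair, against at most 57.5% in any of the 6 same-arm comparisons. These shares lean against a wrong label and do not exclude it. Excision in only part of the cells could not be told apart from a difference between the marrows: the slope of the number 4 pair on the BM change over 1725 genes was 0.107, below the 0.162 and 0.1503 of the number 2 pairs, while its median change in the BM direction over the 315 genes was 0.16, above their 0.10 and 0.08.

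Granulocyte, granule and eosinophil genes were higher in BM Cre cells. Other probes were counted for all genes at least 4-fold higher in BM Cre cells, not for these lists alone. Of 117 such probes of 86 genes, 116 (99.1%) were higher too. Only detected probes entered, so a silent probe of a gene undetected in the other groups could not count. This share therefore cannot decide on effects of single probes. Where genes changed 16-fold, 30 other probes held a median of 79.0% of the log2 difference, 2 of them under 25%. Granulocytic cells diluting mast-like cells remain possible: the mast cell and basophil list moved both ways (adjusted p = 0.679 with an estimated correlation), which decides nothing. A change in the cells present and a change within cells cannot be told apart here. An effect of Cre itself stays open and untested, since no Cre-treated cells without loxP sites were among the samples.

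In both arms 25 genes were at least 16-fold apart between CD34+ and BM cells, 6 higher and 19 lower in CD34+ cells. Effects of single probes cannot be told apart from a change in the gene: other probes held a median of 50.4% of the log2 difference, over only 11 probes of 8 of these genes (0 with the opposite sign, 1 with under 25% of the difference), against 79.0% over 30 probes for Cre in BM cells. The CD34 sort gave no sign in its own marker, with a Cd34 log2 difference of 0.0858, and this decides little because protein was sorted and transcript measured. Any difference in culture, day or chip is confounded with population.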

How the results depend on the processing

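The arrays of marrow number 2 only, averaged repeats for the last 2 comparisons, and averaged repeats with a number block were chosen after the data were seen.

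The CD34+ count of 75 stayed within 1.5 times with no background correction, median scaling, the authors' table, other filters, the mean of probes and no trend (50 to 82). It was 18 with the 6 arrays alone, 268 with marrow number as a replicate block, 8 with number and repeat as that block, 2 with number by arm as a random block, 11 with the repeats averaged, 31 with these averaged and blocked by number, and 1150 with number 2 only. Without 1 array it ran from 25 to 1051. It was 25 without control F2-1, control F2-2 or Cre F2-1, and 26 without Cre F2-2. It was 118 without control F4 and 1051 without the array labelled number 4 Cre. In these last fits, and with number 2 only, a CD34+ arm held only repeats of number 2, which are not independent marrows. The cause of the shifts was not tested.

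The BM count of 1725 was 837 with the authors' table and 2839 with repeat number as a replicate block, and ran from 1126 (without control 3) to 2141 (without Cre 3), with 1143 without Cre 1. The count of 593 differing effects was 210 with the authors' table, 949 with the replicate block, 316 with repeats averaged and 1175 with number 2 only, and 424 to 878 without 1 array. The count of 3916 between control cells was 2486 with the authors' table and 3027 to 4015 without 1 array. Of 83 probes at the floor of that table in the CD34+ columns and over 500 by scanner on the BM Cre arrays, 78 stood at 24 in its BM columns, which by construction gives no BM change. The cause of the other shifts was not tested. The correlation of 0.343 stayed between 0.281 and 0.381 in the alternatives run.

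Signs that reversed with the authors' table had values of 0 for the T and NK cell list in BM cells, the stroma and endothelium list for the differing effects and the late granulocyte list between control cells, 0.13 for Ly6c1, 0.87 for Gpnmb and 0.0595 for Slpi between control cells. Without a filter Cd80 (−0.0889) and Hemgn (−0.0466) reversed in BM cells, and with the mean of probes Rab27b (−1.04) and Ddx21 (0.31) between control cells. The ribosome list for the differing effects reversed to −0.36 without BM Cre 3, and passed at 0.50 without BM Cre 2. The cause was not tested.

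Of the results for named genes, 630 of 796 kept direction and side of the threshold in CD34+ cells, 1127 of 1225 in BM cells, 197 of 220 for the differing effects and 1334 of 1419 between control cells. For lists these were 499 of 528, 370 of 408, 544 of 576 and 408 of 432. Signal over background limits the genes seen: 34.4% to 39.2% of probes were detected per array. Chip as a block was not run, as no chip is named.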

Other observations

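No test was run for this part, and the genes named were chosen after their values were seen.

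The BM control arrays differed among themselves in the eosinophil genes Epx, Prg2 and Ear6. Epx stood at 8.41, 7.06 and 5.99 on controls 1 to 3, Prg2 at 13.35, 11.43 and 10.34, and Ear6 at 11.10, 9.00 and 7.83. The macrophage genes Gpnmb and Lyz2 followed another order. Gpnmb stood at 9.68, 13.09 and 11.68 on these arrays and Lyz2 at 10.43, 13.29 and 11.22. Among the CD34+ arrays, the array labelled number 4 Cre was highest for both, with Gpnmb at 10.63 and Lyz2 at 10.50.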
